A study of Mus musculus with 2 samples.

How the data were processed

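Each of the 2 libraries is a 10x Genomics 3' v3.1 single-cell library from mouse brain tissue holding an implanted GL261 tumour and its surroundings, dissociated with an enzymatic kit, per the labels' protocols. The values are UMI counts per gene and barcode, made with Cell Ranger 7.1.0 per the file headers and the submitters' processing notes, and deposited as sparse matrices. The notes also name Seurat 5.0.2 and the genome build mm10, and the role of Seurat is not given in the sources used here. The feature tables list 68886 genes of a combined reference, 36601 of human and 32285 of mouse, and only the mouse genes were used in the comparisons. Gene positions came from GENCODE M21, which covers 32158 of the mouse genes.

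All further steps were computed here with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, scanpy 1.11.5, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9. The filters, cell type markers, gene lists, naming rule and a first set of alternatives were set before the data were examined. Barcodes with at least 500 detected genes and at most 10% mitochondrial UMIs were kept as cells. In the library labelled wild type 3990 barcodes had too few genes and 282 too many mitochondrial UMIs, and in the library labelled knockout 1239 and 555. Doublets were called by Scrublet in each library with an expected rate of 0.8% per 1000 cells and removed. Under the wild type label these were 77 cells (2.48%), where the automatic threshold marked only 0.289% and the expected number of highest scores was taken. Under the knockout label they were 164 cells (2.49%) by the automatic threshold, although 5.26% was expected there. More doublets may therefore remain under the knockout label. Of all barcodes 41.1% and 76.6% were kept. The kept cells held 50130639 and 96566764 UMIs, with quartiles of 6392 to 21617 and of 6702 to 19930 UMIs per cell and median mitochondrial shares of 1.94% and 1.70%.

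Both libraries were clustered together on log-scaled counts per 10000, 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 with a fixed seed. A cluster took the name of the class with the most fixed markers at 20 CPM or more and at least 4-fold above the median of all clusters, if there were at least 3, unless the 10 leading genes held more markers of another class or the cluster had few UMIs and no marker among them. A tie went to the class with the larger mean log2 fold. This named the neuroblast-like cluster 21, which had 8 neuroblast-like and 8 neuron-like markers. The NK cell-like cluster 0 had 8 NK and 7 T cell markers. Names end in "-like" because they rest on these markers only, and clusters without a name keep their number. Tumour cells and host cells are told apart by markers alone. Classes with at least 100 cells in each library were compared: tumour-like, T cell-like, NK cell-like, dendritic-like and monocyte/macrophage-like cells, together with the unnamed clusters 4 and 17. Microglia-like cells, with 99 cells under the wild type label, were not compared gene by gene.

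Within a class, UMIs were summed per library and scaled to CPM. The log2 ratio of the library labelled knockout over the library labelled wild type carries an exact 95% interval conditional on the summed counts. Genes with at least 100 UMIs in the class were measured, and 3 counts replaced a count of 0 in ratios, which are then lower bounds. A gene was called higher or lower by size alone, at 1.5-fold for members of lists and 2-fold for counts over all genes. For each list the median log2 ratio was set against 10000 random lists of the same size matched on mean CPM, and its counting spread came from 1000 Poisson redraws. No p-values were computed. On counts simulated by Poisson draws for the tumour-like class (12569 genes, 200 of them changed 2-fold), the intervals covered the true ratio for 95.3% of genes, the direction was right for 100% of changed genes, and 30 of 400 random lists fell outside the central 95%. The intervals assume such counting error alone, so this checks the computation. It does not show that they cover the spread between cells, clusters or animals.

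Named genes are those with at least 50 CPM in the library where they are higher that pass a screen against RNA from other cells. For this, the level in the class is at least 20% of the highest in any other class with at least 50 cells in that library. Under the wild type label this left out oligodendrocyte-like (30), neuroblast-like (27) and endothelial-like (20) cells. Genes higher under that label were therefore not screened against RNA from these classes. Mitochondrial, ribosomal protein, haemoglobin, sex-linked, immunoglobulin and numbered genes were left out. The 12 highest and 12 lowest were named in tumour-like and T cell-like cells and the 5 highest and 5 lowest elsewhere, with the T-type channel genes always, and from the lists described, members among the 4 with the largest differences and the member with the most UMIs. Some genes that this rule names are not reported here. Tsix was kept by this rule, which names only Xist and 4 Y-linked genes as sex-linked. Mx1 and Clec7a, members of 2 lists, were not analysed here. Cells were sorted by sex-linked UMIs after Xist and the Y-linked genes had been seen.

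Alternatives set beforehand were a looser cell filter (at least 200 genes, at most 25% mitochondrial UMIs), called doublets kept, resolution 0.5, genes centred within each library before the principal components, median-of-ratios scaling, the mean over cells in place of sums, a limit of 30 UMIs per gene, all barcodes, and cells thinned to 2000 UMIs. After seeing the data, clusters of a class weighted alike, only list members passing the screen, and only cells with Y-linked and no Xist UMIs were added. Human genes were left out of the comparisons.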

Results

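Single-cell RNA profiles were collected from the brains of mice that carried GL261 tumours, 24 days after the tumour cells were implanted. GL261 is a mouse glioma line that grows in C57BL/6 hosts and serves as a model of glioblastoma. The hosts were labelled either C57BL/6 wild type or Cacna1h knockout, Cacna1h being the gene of Cav3.2, a T-type calcium channel that opens at low voltage. The implanted cells have their own Cacna1h genes, so the host genotype was the intended difference, and the title of the series places its question on T-type channels of the microenvironment. There was 1 library per group, and how many animals went into each library is not given in the sources used here. The library labelled wild type held 7382 barcodes and 54567114 UMIs, and the library labelled knockout 8369 barcodes and 103281480 UMIs. After filtering, 3033 and 6411 cells were kept, with medians of 12166 and 10851 UMIs and of 3553 and 3262 genes per cell. With 1 library per group no difference below has a replicate check, no test of the genotype was possible, and all intervals cover counting error only.

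Cacna1h transcripts were more abundant in the library labelled knockout. Its kept cells held 158 Cacna1h UMIs, or 1.64 CPM (counts scaled to the mouse UMIs of the same cells; exact Poisson 95% interval 1.39 to 1.91), against 8 UMIs in the library labelled wild type, or 0.160 CPM (0.0689 to 0.314). The difference was 10.3-fold (5.08 to 24.2), and over all barcodes it was 6.91-fold (3.93 to 13.2). In all host classes together 119 UMIs stood against 7, a 5.45-fold difference (2.56 to 13.8). In the immune classes among them, 109 UMIs in the library labelled knockout stood against 1 in the library labelled wild type, a 34.9-fold difference (6.13 to 1389). Within the library labelled knockout, Cacna1h was counted at 2.48 CPM in T cell-like cells, 3.72 CPM in monocyte/macrophage-like cells, 1.90 CPM in microglia-like cells and 4.66 CPM in neuroblast-like cells. Tumour-like cells held 3 Cacna1h UMIs in the library labelled knockout (0.0919 CPM, 0.0190 to 0.269) and 0 in the library labelled wild type, where the upper limit of the interval is 0.164 CPM. Oligodendrocyte-like cells, singled out after their values were seen, went the other way in UMIs: 5 in 3 of 30 cells (15.1 CPM) under the wild type label and 4 in 4 of 107 cells (2.96 CPM) under the knockout label, 5.11-fold lower in the latter (1.10 to 25.8). The intervals of their shares of cells overlap (2.11% to 26.5% and 1.03% to 9.30%).

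The share of kept cells with a Cacna1h UMI was 0.198% (6 cells, exact binomial 95% interval 0.0726 to 0.430) under the wild type label and 2.42% (155 cells, 2.06 to 2.82) under the knockout label. In tumour-like cells of the library labelled knockout, which are deeper at a median of 26725 UMIs, the share was 0.283% (0.0585 to 0.826). After every cell was thinned to 2000 UMIs, leaving out 66 and 187 shallower cells, the shares were 0.101% (0.0209 to 0.295) and 0.418% (0.273 to 0.611). Cacna1h (ENSMUSG00000024112) lies on the minus strand of chromosome 17 from 25374285 to 25433783 in mm10. These libraries count tags near the 3' ends of transcripts. Which exons the allele lacks is not given in the sources used here, and a tag outside the deleted part checks nothing about the deletion. Since Cacna1h was higher under the knockout label, the groups are called the library labelled wild type and the library labelled knockout throughout, and each direction below is a direction between these labels.

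The other T-type channel genes were also sparse. Cacna1g, which encodes Cav3.1, had 6 UMIs in the kept cells of the library labelled wild type and 26 in those of the library labelled knockout, a 2.25-fold difference in CPM whose interval includes no difference (0.906 to 6.68). Of these, 4 and 18 UMIs fell in cluster 13, an unnamed cluster led by Klk1, Ccr9, Ly6d and Siglech, at 7.15 and 7.02 CPM. Cacna1i, which encodes Cav3.3, had 15 and 85 UMIs, of which B cell-like cells held 12 and 75. Within B cell-like cells its level was 44.3 CPM (22.9 to 77.4) under the wild type label and 22.9 CPM (18.0 to 28.7) under the knockout label, a difference that was not detectable at this depth.

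Genes of the sex chromosomes divided the libraries. In host classes of the library labelled wild type, the Y-linked genes Ddx3y, Uty, Eif2s3y and Kdm5d together stood at 279 CPM (271 to 287), while Xist, the RNA that coats the inactive X chromosome of female cells, had 0 UMIs. In host classes of the library labelled knockout, Xist stood at 560 CPM (553 to 566) and the Y-linked genes at 60.3 CPM (58.1 to 62.5). Of its 4549 host cells, 3118 had Xist UMIs and no Y-linked UMI, 809 had Y-linked UMIs and no Xist UMI, 99 had both and 523 had neither. The library labelled knockout thus held cells of both kinds in each host class of at least 20 cells per library. Among these classes its Y-linked level ranged from 14.1% of that under the wild type label in NK cell-like cells and 14.7% in dendritic-like cells to 55.6% in oligodendrocyte-like cells, and in the unnamed cluster 4 it was 7.16% (5.89 to 8.64). Tumour-like cells had Y-linked genes at 1.74 and 1.07 CPM and Xist at 0.312 and 9.59 CPM.

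**Figure D1:**
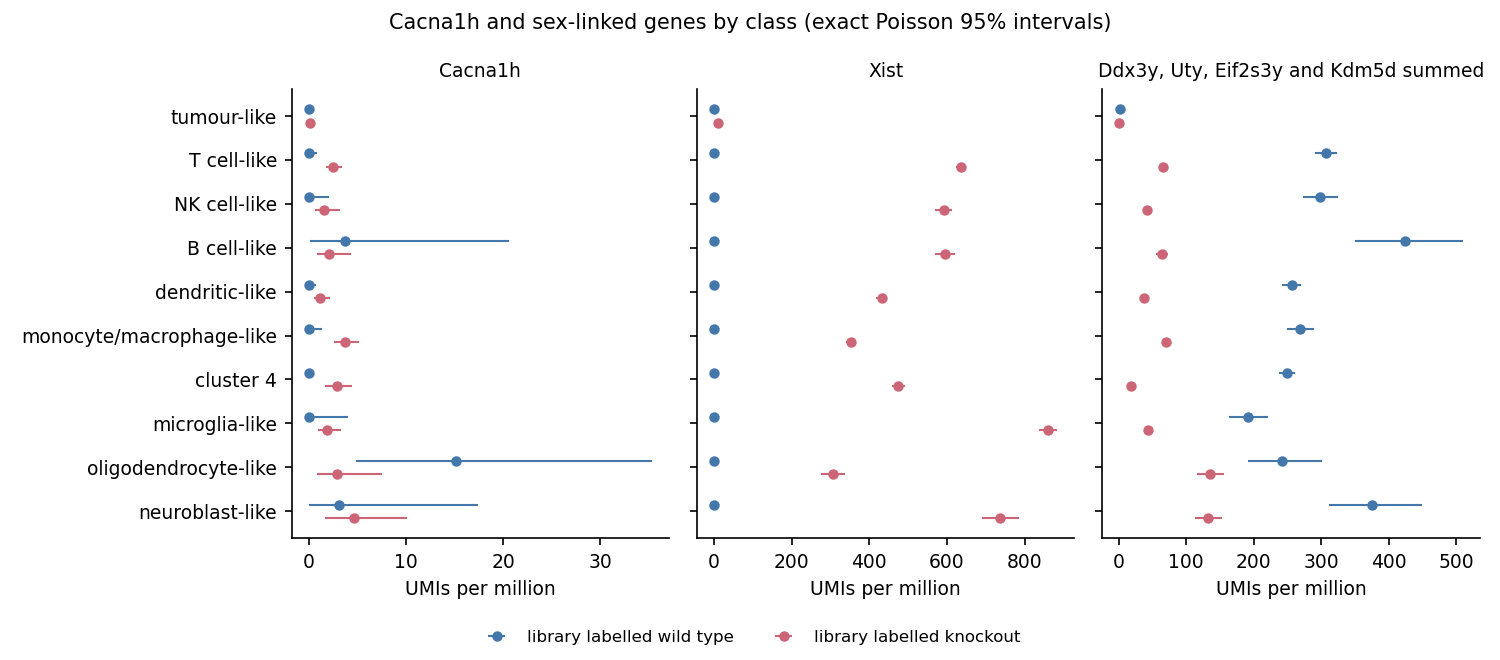
CPM of Cacna1h (left), Xist (middle) and 4 summed Y-linked genes (right) by cell class, with exact Poisson 95% intervals, in blue for the library labelled wild type and red for the library labelled knockout (1 library each). Cacna1h lies higher under the knockout label in T cell-like cells (0 and 2.48 CPM) and lower in oligodendrocyte-like cells (15.1 and 2.96 CPM); Xist has 0 UMIs in host classes under the wild type label.

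The composition of the tissue differed between the libraries. Tumour-like cells made up 22.2% of the kept cells under the wild type label (672 cells, exact binomial 95% interval 20.7 to 23.7) and 16.5% under the knockout label (1059 cells, 15.6 to 17.5), a share 1.34 times as large under the wild type label (1.22 to 1.48). T cell-like cells were 18.4% of the cells under the wild type label and 23.2% under the knockout label, a ratio of 1.26 (1.15 to 1.40), and B cell-like cells 2.08% and 5.07%, a ratio of 2.44 (1.86 to 3.25). Microglia-like cells, the resident macrophages of the brain, were 3.26% and 7.22% of the cells, a ratio of 2.21 (1.78 to 2.78). NK cell-like cells were 8.28% and 10.2%, a ratio of 1.23 (1.06 to 1.43), and dendritic-like cells 11.3% and 9.02%, 1.25 times as large under the wild type label (1.09 to 1.44).

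Macrophages were divided among several clusters. Monocyte/macrophage-like cells were 9.13% (8.13 to 10.2) under the wild type label and 12.4% (11.6 to 13.2) under the knockout label, a ratio of 1.35 (1.18 to 1.56). Cluster 4, which has macrophage markers but is led by H2-M2, Adamdec1, Mmp12 and Ccl24 and was left unnamed because a border macrophage marker, Mrc1, is among its leading genes, went the other way, with 12.7% (11.5 to 13.9) and 4.32% (3.84 to 4.85). At a coarser clustering resolution of 0.5 all 662 cells of cluster 4 joined the monocyte/macrophage-like class, and the log2 ratio of the class's shares turned from 0.44 to -0.40. Unnamed clusters held 22.6% and 12.5% of the cells in all. Oligodendrocyte-like cells (30 and 107), neuroblast-like cells (27 and 97), endothelial-like cells (20 and 36) and neutrophil-like cells (10 and 9) were few.

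Among tumour-like cells the subclusters differed in proportion. Cluster 6, led by Col2a1, Acot1 and Enpp2, held 54 cells under the wild type label and 356 under the knockout label, while cluster 12, led by Sncaip, Cntn1 and Nts, held 186 and 96. Cluster 15, led by the cell division genes Cdc20, Ube2c and Cenpf, held 126 of 672 tumour-like cells under the wild type label and 132 of 1059 under the knockout label. As a share of all kept cells, which also carries the lower tumour-like share, it made up 4.15% (3.47 to 4.93) and 2.06% (1.73 to 2.44). Cluster 2 held the remaining 306 and 475 cells. With called doublets kept, cluster 6 and 567 of the 781 cells of cluster 2 fell into a cluster that could not be named, and the log2 ratio of the tumour-like shares went from -0.42 to -1.74. Dissociation and cell capture can set such shares. The library labelled wild type had 2464 barcodes (33.4%) under 200 UMIs against 85 (1.02%) in the library labelled knockout. All of these barcodes held a UMI of a human gene, with 2497 and 171 such UMIs in total. Their number therefore need not reflect dissociation or capture. Between cells with Y-linked UMIs and no Xist UMI in both libraries, the log2 ratio of the NK cell-like shares turned from 0.30 to -0.14, and that of the dendritic-like shares went from -0.33 to -1.14.

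**Figure D2:**
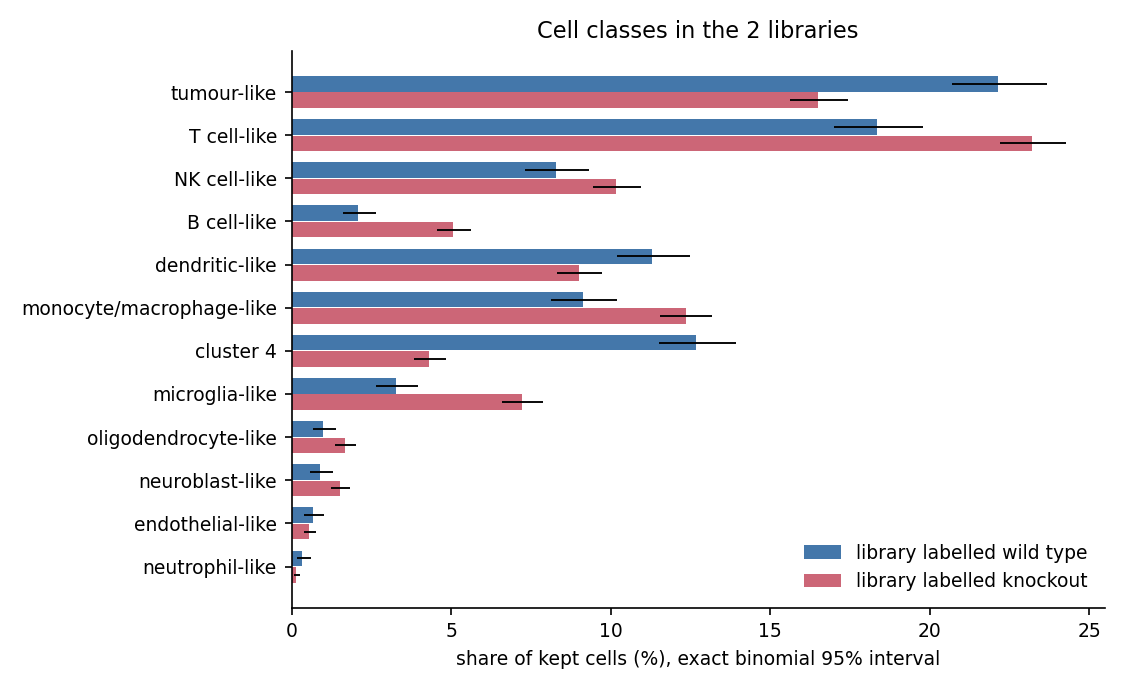
Share of kept cells in each class (percent) with exact binomial 95% intervals, in blue for the library labelled wild type (3033 cells) and in red for the library labelled knockout (6411 cells). Tumour-like, dendritic-like and cluster 4 cells take larger shares under the wild type label, T, NK and B cell-like, monocyte/macrophage-like and microglia-like cells under the knockout label.

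Tumour-like cells under the knockout label had higher levels of antigen presentation and interferon genes and lower levels of genes for cell division, glycolysis, sterol synthesis and the oligodendrocyte lineage. The cell division difference depended on the setting. The median log2 ratio of G2/M genes was -0.69, but -0.084 with the clusters weighted alike and 0.32 with called doublets kept. Of 12573 measured genes, 487 were at least 2-fold higher and 361 at least 2-fold lower under the knockout label by size alone, and 262 and 317 of these passed a screen against RNA from other cells. The counts were 780 and 315 with the looser filter, where the class holds 119 of the 124 neuroblast-like cells, 247 and 212 with called doublets kept, where it lacks cluster 6 and most of cluster 2, and 259 and 243 with the clusters weighted alike, a setting chosen after seeing the data. For the 317 lower genes the screen did not cover oligodendrocyte-like, neuroblast-like or endothelial-like cells, which were too few under the wild type label. Among the genes named by a rule set before the data were examined, Gbp4, an interferon-induced GTPase, stood at 104 and 342 CPM (log2 ratio 1.72, 95% counting interval 1.65 to 1.78). Ciita, the master regulator of MHC class II transcription, was 3.00-fold higher, and the interferon-induced genes Ifit3 and Ifit3b were 2.90-fold and 2.88-fold higher. Apoc1, which encodes an apolipoprotein, stood at 5.61 and 58.3 CPM (log2 ratio 3.38, 3.12 to 3.65). S100b, a calcium-binding protein of glia, was 3.46-fold higher at 96.1 and 333 CPM. Polr2l, Usp50, Col4a5, Cp, Aebp1 and Acot1 were 2.98-fold to 5.20-fold higher.

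Krt8, which encodes a keratin, was the gene furthest below among those named, with 113 CPM under the wild type label and 2.73 CPM under the knockout label (log2 ratio -5.38, -5.70 to -5.07). The lactate exporter gene Slc16a3 was 12.2-fold lower, Tmeff2 15.9-fold lower and Opcml, which encodes an adhesion molecule of neurons, 10.7-fold lower. Genes for 3 enzymes of sterol synthesis were lower: Hmgcs1 by 5.97-fold, Cyp51 by 4.10-fold and Fdps by 3.99-fold. Cyp51 and Fdps were also at least 1.5-fold lower in all 6 host groups compared. Cntn1, Nts, Agbl1 and Lrp1b were 4.48-fold to 5.08-fold lower. S100b, Apoc1 and Acot1 are among the leading genes of cluster 6 and Cntn1, Nts and Agbl1 among those of cluster 12. With the clusters weighted alike in both libraries, a setting chosen after seeing the data, their log2 ratios went from 1.79 to 1.06, 3.38 to 2.07, 1.58 to 0.75, -2.16 to -0.88, -2.34 to -1.17 and -2.24 to -1.65, and that of Krt8 from -5.38 to -5.06. With called doublets kept the 6 log2 ratios were 1.17, 2.42, 0.19, -1.11, -1.50 and -2.03, and that of Krt8 was -3.94, the class then lacking cluster 6 and 567 of the 781 cells of cluster 2. Malat1, a nuclear RNA, took 0.595% of the UMIs of tumour-like cells under the wild type label and 1.33% under the knockout label.

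Of 23 measured interferon response genes in tumour-like cells, 17 were at least 1.5-fold higher under the knockout label and none lower (median log2 ratio 0.74, counting spread 0.70 to 0.79), above all 10000 random lists matched on expression as a description of these libraries. Igtp stood at 392 and 952 CPM, Gbp2 was 2.33-fold higher and Bst2 1.60-fold higher. Of 14 MHC class I presentation genes 10 were higher (median 0.63, 0.62 to 0.68), with H2-K1 at 953 and 1706 CPM, B2m at 1233 and 2005 CPM and Tap2, the peptide transporter subunit, 1.98-fold higher. All 7 measured MHC class II genes were higher (median 1.49, 1.45 to 1.52), though only 3 passed the screen against RNA from other cells (median 1.14), and H2-Aa at 307 and 961 CPM and Cd74 at 836 and 2002 CPM were among those that did not. Markers of other cell types moved with these groups: of 9 measured T cell effector genes in tumour-like cells, 7 were higher and 1 lower (median 2.15), and of 10 homeostatic microglia genes 5 were higher and 3 lower (median 0.53), and no member of either list passed the screen. Of 15 astrocyte genes 8 were higher and 1 lower (median 0.62, 0.54 to 0.66), including Clu at 1.92-fold and, below the 1.5-fold limit, Mt1 at 1.34-fold.

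Cell division genes were lower under the knockout label in tumour-like cells, with 13 of 24 S phase genes (median log2 ratio -0.61, -0.63 to -0.54) and 16 of 25 G2/M phase genes (median -0.69, -0.73 to -0.64) at least 1.5-fold lower and none higher. Rrm2, a subunit of ribonucleotide reductase, stood at 57.6 and 27.1 CPM and the cyclin gene Ccnb1 at 71.2 and 33.0 CPM, while Slbp and Top2a were 1.20-fold and 1.38-fold lower. With the clusters weighted alike the medians were -0.25 and -0.084, and with called doublets kept, where the class lacks cluster 6 and most of cluster 2, the G2/M median was 0.32. Hypoxia and glycolysis genes were lower, with 11 of 18 at least 1.5-fold lower and none higher (median -0.63, -0.71 to -0.59). Lactate dehydrogenase A, Ldha, stood at 368 and 177 CPM, the hypoxia-induced carbonic anhydrase Car9 at 6.68 and 0.736 CPM and Gapdh at 1425 and 1027 CPM. Of 22 oligodendrocyte lineage genes 12 were lower and 1 higher (median -0.67, -0.71 to -0.62), with the myelin genes Opalin 28.3-fold and Mag 5.64-fold lower and Bcas1, the member with the most UMIs, 1.20-fold lower. Genes lower under the knockout label were not screened against RNA from oligodendrocyte-like cells, so such RNA could not be told apart here.

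Lists tied to neuronal processes were measured in tumour-like cells. Of 16 measured synapse genes 1 was at least 1.5-fold higher and 2 were lower (median log2 ratio -0.018, -0.17 to 0.061; 43.2th percentile of the random lists), with Syn1, a synaptic vesicle protein gene, 2.12-fold lower at 14.2 and 6.68 CPM. Of 20 neuronal differentiation and axon growth genes 1 was higher and 5 were lower (median -0.17, -0.25 to -0.13), with a median of -0.38 over the 16 that passed the screen. For genes lower under the knockout label that screen did not cover neuroblast-like cells. Sox11 was 7.32-fold lower, Gap43 3.43-fold lower and Tubb2b 1.48-fold lower. With the looser cell filter the Sox11 log2 ratio turned from -2.87 to 0.79 and the list median to 0.34, but 119 of the 124 neuroblast-like cells were then counted as tumour-like. Only 4 voltage-gated calcium channel genes could be measured (median -0.42), of which Cacnb4 was 3.08-fold and Cacna1b 1.94-fold lower, each at under 12 CPM. The 21 calcium handling genes had a median of 0.067, and medians between -0.27 and 0.067 were found for the mesenchymal state (-0.14, Col1a1 being 13.9-fold and Vim 1.14-fold lower), immediate early genes (-0.099, Jun being 1.39-fold higher and Egr1 1.42-fold lower), p53 targets (-0.18), ER stress (-0.039), heat shock (-0.19) and angiogenesis (-0.27). Neural stem and progenitor genes had a median of 0.39 over 15 members and -0.023 over the 12 that passed the screen, with Hes1 2.53-fold higher and Id1 2.23-fold lower.

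**Figure D3:**
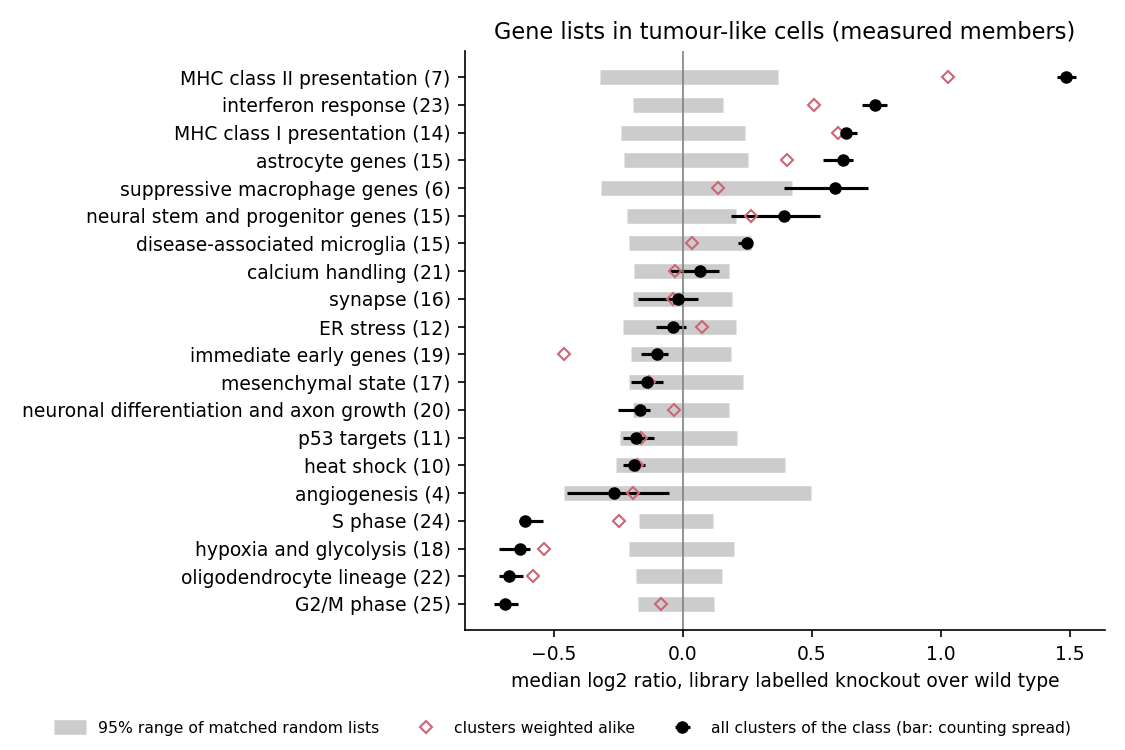
Median log2 ratio of CPM (library labelled knockout over library labelled wild type) of each gene list in tumour-like cells, with the number of measured members in brackets. Black points and bars give the median and its counting spread, grey bars the 95% range of matched random lists, and open red diamonds the median with the clusters of the class weighted alike. MHC class II (1.49), interferon (0.74) and MHC class I (0.63) lists lie above the grey bars, and the S phase (-0.61), hypoxia and glycolysis (-0.63), oligodendrocyte (-0.67) and G2/M (-0.69) lists below them, where weighting the clusters alike moves G2/M to -0.084.

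Dendritic-like cells showed the widest interferon difference among the host classes compared. Of 23 measured interferon response genes 22 were at least 1.5-fold higher under the knockout label and none lower (median log2 ratio 1.38, 1.27 to 1.43). Cxcl10 and Cxcl9, chemokines that attract T cells, stood at 132 and 472 CPM and at 325 and 1066 CPM. Ifit3 had a log2 ratio with an interval of 1.72 to 2.29, Ifit1 was 3.46-fold higher and Ifi27l2a 4.45-fold higher. Timd4 was 3.70-fold higher, and H2-Q7 led the MHC class I list at 313 and 600 CPM (list median 0.36, 0.31 to 0.40), whereas the 8 MHC class II genes had a median of -0.27 (-0.32 to -0.23), H2-DMb1 being 1.43-fold lower. Dendritic-like cells also had lower division genes, with 20 of 22 S phase genes (median -0.83, -0.94 to -0.74) and 17 of 23 G2/M genes (median -0.71, only 2 members passing the screen against RNA from other cells) at least 1.5-fold lower, among them Pcna at 105 and 57.7 CPM, Gins2 at 2.43-fold and Ccnb2 at 2.55-fold lower. Fosb and Fos were 2.22-fold and 1.57-fold lower, in an immediate early list with a median of -0.15, and the heat shock median was -0.21.

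Over all 8586 genes measured in dendritic-like cells, 317 were at least 2-fold higher and 114 at least 2-fold lower under the knockout label, of which 174 and 84 passed the screen against RNA from other cells. When each cell weighed the same, the counts were 277 and 236, and between cells with Y-linked UMIs and no Xist UMI in both libraries 98 and 140. Abca13, Gfer, Sult1a1, Ppp1r14a and Irs2 were the 5 lowest named genes, 2.91-fold to 4.82-fold lower. The clusters of the class were unevenly divided: cluster 10, led by Ccr7, held 94 and 228 cells, cluster 11, led by Ccl17 and Cd209a, 98 and 216, and the Xcr1-positive clusters 16 and 32 held 130 and 115, and 21 and 19. Between cells with Y-linked UMIs and no Xist UMI in both libraries, the interferon median was 1.18, the S phase median -0.48 and the G2/M median 0.26.

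Ifi202b, a member of the interferon-induced Ifi200 family on chromosome 1, was counted only under the knockout label in the 4 compared host groups where it was measured. With 0 UMIs under the wild type label it was at least 20.9-fold higher in T cell-like cells (13.8 CPM, not passing the screen against RNA from other cells), at least 168-fold higher in monocyte/macrophage-like cells (189 CPM), at least 191-fold higher in dendritic-like cells (117 CPM) and at least 392-fold higher in cluster 4 (165 CPM), each bound set against 3 counts. Within the library labelled knockout its level in cells with Xist UMIs and no Y-linked UMI was 3.58-fold, 2.34-fold, 1.45-fold and 2.42-fold that in cells with Y-linked UMIs and no Xist UMI, where it stood at 4.45, 96.8, 88.1 and 71.0 CPM. Between cells of the latter kind in both libraries the log2 bound in monocyte/macrophage-like cells was 6.23 instead of 7.40. Its relatives moved apart: Ifi213 was lower under the knockout label, at 146 and 24.1 CPM in monocyte/macrophage-like cells, 66.1 and 11.8 CPM in T cell-like cells and 14.7-fold lower in cluster 4, Ifi206 was 3.76-fold lower in monocyte/macrophage-like cells, 2.44-fold lower in T cell-like cells and 2.31-fold lower in NK cell-like cells, and Ifi214 was 4.76-fold higher in NK cell-like cells. These genes are close copies of each other, so reads can be divided among them in counting.

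Monocyte/macrophage-like cells differed in both directions among inflammatory genes. Nos2, the inducible nitric oxide synthase, stood at 12.4 and 64.2 CPM (log2 ratio 2.38, 1.87 to 2.93), the acute phase gene Saa3 at 5.62 and 62.2 CPM (3.47, 2.74 to 4.32) and the chemokine gene Ccl5 at 548 and 1945 CPM (1.83, 1.75 to 1.91). T cell effector genes, a list that holds Ccl5, had 4 higher and 1 lower of 5 measured members in these cells (median 1.53). Only 2 of them passed the screen against RNA from other cells (median 0.54). Chil3, a marker of alternatively activated macrophages, was lower at 294 and 67.0 CPM, and Pf4 stood at 77.1 and 21.4 CPM and March3 was 3.65-fold lower. Of 18 inflammatory cytokine genes 5 were higher and 5 lower (median 0.28, and 0.065 between cells with Y-linked UMIs and no Xist UMI in both libraries), among the latter Cxcl2 at 860 and 338 CPM, while Il1b, the member with the most UMIs, was 1.13-fold lower. Of 11 suppressive macrophage genes 1 was higher and 3 were lower (median -0.13): Vegfa stood at 157 and 236 CPM, Mrc1 was 2.28-fold lower and Arg1 stood at 586 and 644 CPM. Disease-associated microglia genes had a median of -0.18, with Spp1 2.27-fold and Lpl 4.28-fold lower.

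The interferon list was higher in monocyte/macrophage-like cells by a median log2 ratio of 0.37 (0.33 to 0.43; 5 of 23 members at least 1.5-fold higher). MHC class I genes had a median of 0.25, with H2-Q7 1.72-fold higher, and hypoxia and glycolysis genes a median of 0.28, with Tpi1 1.55-fold higher. Gdf15 was 5.81-fold lower, in a p53 target list with a median of -0.24, and the mesenchymal state list had a median of -0.0053. Between cells with Y-linked UMIs and no Xist UMI in both libraries the interferon median was 0.048. Of 8126 measured genes 100 were at least 2-fold higher and 55 at least 2-fold lower under the knockout label, and between such cells 57 were higher and 91 lower. Of the 100 and 55 genes, 66 and 48 passed the screen against RNA from other cells.

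Cluster 4 had lower levels of Lpl and Ear2 under the knockout label. Lpl, the gene of lipoprotein lipase, stood at 98.4 and 3.63 CPM (log2 ratio -4.76, -5.41 to -4.18), and Ear2, Adgrl3 and Gbp2b were 19.3-fold, 21.3-fold and 7.45-fold lower. Pdpn, F10, Junos and Tnfaip8l3 were 3.43-fold to 5.27-fold higher. The interferon median was 0.37 (0.26 to 0.42), with Ifi44 2.40-fold higher, whereas inflammatory cytokine genes had 4 higher and 8 lower members of 17 (median -0.28, -0.51 to -0.11), S phase genes a median of -0.40 and immediate early genes a median of -0.28. Among its 277 cells under the knockout label, 15 had Y-linked UMIs and no Xist UMI, and between such cells of both libraries the interferon median turned to -0.21, the S phase median to 0.35, the inflammatory cytokine median to 0.24 and the F10 log2 ratio to -0.29.

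T cell-like cells were compared over 9545 measured genes. Of these 117 were at least 2-fold higher and 37 at least 2-fold lower under the knockout label, against 18 and 58 between cells with Y-linked UMIs and no Xist UMI in both libraries. Of the 117 and 37 genes, 60 and 26 passed the screen against RNA from other cells. The clusters of the class were unevenly divided: cluster 5, led by Ccl1 and Ifng and with Lgals7 and Csf2 among its leading genes, held 83 and 367 cells, cluster 8, with Gzmf, Gzmk and Klra5, 129 and 217, and cluster 22, with Il17a, 21 and 94. Il17a, the cytokine of type 17 lymphocytes, was 2.95-fold higher (log2 ratio 1.56, 1.25 to 1.89), Cd40lg, a signal of activated helper T cells, stood at 26.1 and 62.3 CPM, and Spp1 at 73.1 and 164 CPM. Ifi27l2a and Ifitm1, both interferon-induced, were 2.22-fold and 1.99-fold higher, and Dnah8, Glo1, Lgals7, Klra5 and Furin 1.96-fold to 5.19-fold higher. Cytokine genes were also among those lower, with Csf2 1.95-fold and Ccl1 1.78-fold lower, and Fgf13, Cables1, Zfp52, Ppil1, Rpa2, Gzmk and Cd160 1.68-fold to 2.11-fold lower. With the clusters weighted alike the log2 ratio of Il17a was 0.55 and that of Lgals7 0.44. Between cells with Y-linked UMIs and no Xist UMI in both libraries they turned to -1.75 and -0.45, and that of Gzmk to 0.33.

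In the lists for T cell-like cells, the interferon median was 0.33 (0.23 to 0.38; 5 of 23 members higher), and -0.19 (-0.29 to -0.086) between cells with Y-linked UMIs and no Xist UMI in both libraries. S phase genes had a median of -0.46 (-0.55 to -0.39; 5 of 23 lower), with Ung 1.88-fold and Mcm6 1.17-fold lower, while G2/M genes had a median of -0.014. Heat shock genes had a median of -0.31 (-0.35 to -0.29), with Dnajb1 1.55-fold and Hsp90ab1 1.25-fold lower. T cell effector genes had a median of -0.078 (2 of 14 lower), Gzma being 1.67-fold and Ifng 1.39-fold lower, and checkpoint genes a median of 0.091, Lag3 being 1.55-fold and Ctla4 1.21-fold higher.

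NK cell-like cells differed in granzyme genes of 1 cluster on chromosome 14, in both directions. Gzmg stood at 2.81 CPM under the wild type label and 644 CPM under the knockout label, Gzmf at 38.3 and 885 CPM and Gzme at 55.7 and 213 CPM, while Gzmc was lower at 6555 and 1381 CPM (log2 ratio -2.25, -2.29 to -2.20). In T cell-like cells Gzmf was 9.73-fold higher and Gzmg 2.07-fold lower, where with the looser filter their log2 ratios were 1.13 and 0.30 and with doublets kept 0.99 and 0.066. In both of these settings cluster 17 was named T cell-like, with 233 and 231 of its 233 cells. In cluster 17, a cluster of dividing cells with T and NK markers, Gzmf, Gzmc and Gzmd were 13.5-fold, 7.63-fold and 26.9-fold lower, along with the NK receptor gene Ncr1 at 7.56-fold and Clnk at 6.12-fold. These granzymes are close copies of each other, so reads can be divided among them in counting. Gzmc, Gzmd, Ncr1 and Clnk are also among the leading genes of the NK cell-like cluster 0. Whether the mix of T and NK cells within cluster 17 differed between the libraries was not tested. When each cell weighed the same, the Gzme log2 ratio in NK cell-like cells turned from 1.93 to -0.19. Dnah8 was 7.47-fold higher, and Sema6d, Zfp52 and Nrgn 2.07-fold to 2.14-fold lower.

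The interferon list in NK cell-like cells had a median of 0.36 (0.24 to 0.48; 7 of 22 members higher and 1 lower), and -0.10 (-0.34 to 0.19) between cells with Y-linked UMIs and no Xist UMI in both libraries. S phase genes had a median of -0.30, with Mcm2 1.83-fold lower, and heat shock genes a median of -0.16, with Hsp90ab1 1.43-fold lower. In cluster 17, 12 of 16 interferon genes were higher (median 0.82, 0.63 to 0.93, and 0.67, 0.48 to 0.94, between cells with Y-linked UMIs and no Xist UMI in both libraries), Ifi27l2a at 338 and 1067 CPM, and 0 of 23 S phase genes passed 1.5-fold in either direction (median 0.033). Dnah8, Cpm, Atf5 and St6gal1 were 4.10-fold to 7.42-fold higher in cluster 17, and Tsix, the antisense partner of Xist, had 1 and 133 UMIs. MHC class II genes were higher in T cell-like cells, NK cell-like cells and cluster 17 by medians of 0.67, 0.51 and 1.13, but no measured member passed the screen against RNA from other cells, and between cells with Y-linked UMIs and no Xist UMI in both libraries the T cell-like median turned to -0.35.

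**Figure D4:**
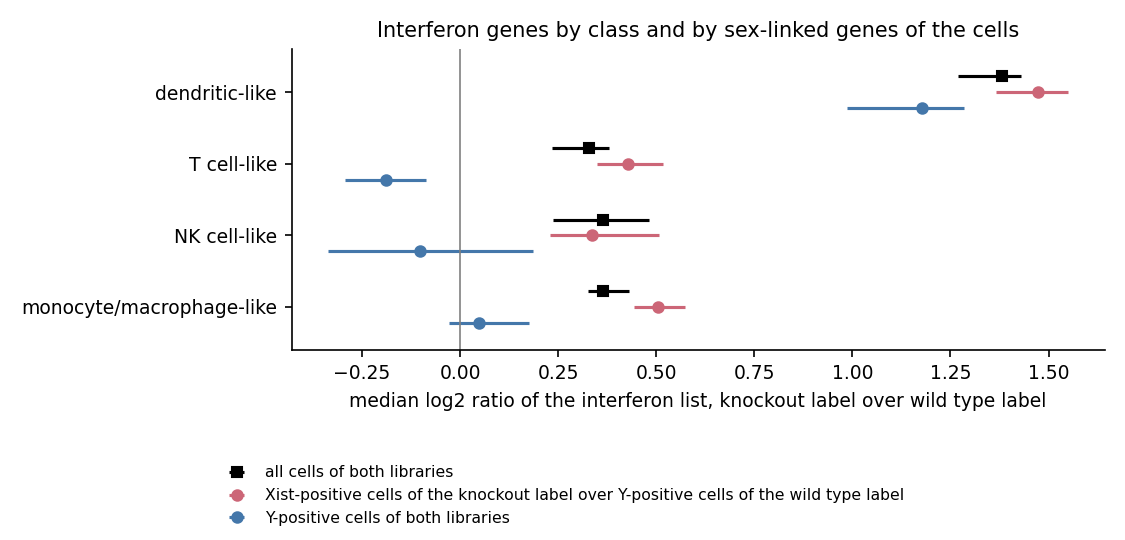
Median log2 ratio of the interferon response list in 4 host classes, library labelled knockout over library labelled wild type, with counting spread. Black squares use all cells, red circles cells with Xist and no Y-linked UMIs under the knockout label against cells with Y-linked UMIs under the wild type label, and blue circles cells with Y-linked and no Xist UMIs in both libraries. The blue medians are -0.19 in T cell-like, -0.10 in NK cell-like, 0.048 in monocyte/macrophage-like and 1.18 in dendritic-like cells.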

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

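Of the tests in this part, those of swapped labels, of free RNA for Cacna1h and of the interferon lists were chosen only after the result was seen, and the others were written down before they were run.

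Genes of the human part of the reference had a signal although the tissue is labelled as mouse and these genes were not used in the comparisons: 10781 UMIs in the library labelled wild type and 20272 in the library labelled knockout, with no control sample to set a level. These were alike shares of all UMIs, 0.0198% and 0.0196%. In barcodes of 200 UMIs or more, however, the shares were 0.0152% and 0.0195%, so there the totals did not differ by depth alone.

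The first pattern is Cacna1h, higher in the library labelled knockout. Free RNA from burst cells is argued against by its level in host classes, 25.8 times that in tumour-like cells of the same library (8.62 to 127). For a mixture with wild type animals of 1 sex, Xist-positive and Y-positive host cells under the knockout label had alike levels, a ratio of 0.977 (0.605 to 1.64). This ratio cannot decide, since it would also be near 1 if the knockout allele gives tags. Y-positive host cells stood at 2.41 CPM (1.51 to 3.64) under the knockout label and 0.488 CPM (0.196 to 1.005) under the wild type label. Mixed-in cells at the latter level could not alone give the former. A swap of the 2 labels would put the C57BL/6 wild type hosts under the knockout label, and is argued against by Ifi202b, which is defective in C57BL/6 mice by textbook knowledge and was at least 168 times higher there, whereas a swap with an outside sample stays open. RNA made from a knockout allele also stays open, since the exons it lacks are not given in the sources used here, so the label was not tested by these tags.

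The second pattern is a set of 61 genes shifted alike in host classes, 43 higher and 18 lower under the knockout label. Genes on the X and Y chromosomes were left out, and a gene without a known position was counted in. The sex of the hosts is argued against, as the median shift between Y-positive cells of both libraries was 99.9% of that over all cells. A segment of another strain around Cacna1h stays open: genes within 10 Mb were shifted 4.28 times as often as elsewhere (6 of 205 and 55 of 8048), and 2.79 times (3 of 200 and 43 of 8010) with the named genes left out, among them Gfer, Glo1 and Dnah8 within that distance. This region was not the one with the highest share. Among 172 ranked bins of 10 Mb, chromosome 1 from 170 to 180 Mb, where Ifi202b lies, ranked first (5 of 66). On chromosome 17, 30 to 40 Mb had rank 10 (5 of 123) and 20 to 30 Mb rank 18 (3 of 109). Free RNA or depth stays open too, since over the 40 of these genes measured in tumour-like cells the median absolute log2 ratio was 0.85 there and 1.14 in host cells, 26 being at least 1.5-fold shifted in tumour-like cells in the direction found in host cells. These medians cover a mixed set. In tumour-like cells the log2 ratios of the immunoglobulin genes Igkc and Ighg1 were 5.30 and 6.72. Those of Glo1 and Gfer near Cacna1h were -0.045 and -0.345, and that of Gzmc, lower in host classes, was 2.46. The biological explanation, the host genotype, cannot be set apart from strain with 1 library per group.

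The last pattern is the higher interferon list under the knockout label. Mixed sexes may account for it in T cell-like and monocyte/macrophage-like cells, where the medians between Y-positive cells of both libraries were -0.19 and 0.048, and this stays open in NK cell-like cells at -0.10 (-0.34 to 0.19). In dendritic-like cells and cluster 17 that explanation is argued against by medians of 1.18 (0.99 to 1.28) and 0.67 (0.48 to 0.94). In tumour-like cells different cluster proportions are argued against as the whole cause, since the median was 0.51 with clusters weighted alike. It was 0.74 over all cells, so part of the difference went with the proportions. The limit for this call was also set after the result was seen, and lower than that of the other interferon tests. Sex and animal are not separable here, so any other difference between the animals stays open beside genotype.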

How the results depend on the processing

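Values with clusters weighted alike, with members passing the screen and with Y-positive cells were chosen only after the result was seen. Of all values under the alternatives, 1590 stayed within counting error (counts of genes: within 1.5-fold), 504 moved further without a called result changing sign, and 25 called results changed sign. This tally does not measure robustness, since some settings could hardly move a value. The limit of 30 UMIs leaves each single-gene ratio as it was (164 values), and median-of-ratios scaling shifts all genes of a class by the same factor (164 values). With clusters weighted alike, 78 single-gene values moved and 51 stayed. Unless stated, the cause was not tested. Genes centred within each library and median-of-ratios scaling turned no result. No paired analysis was possible because there is 1 library per group, sharing replicate number 1. Depth limits the T-type channel genes, with 8 Cacna1h and 6 Cacna1g UMIs in the kept cells under the wild type label.

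Shares, as log2 ratios: that of monocyte/macrophage-like cells was -0.40 at resolution 0.5, where cluster 4 joins the class by construction, and 0.69 between Y-positive cells, where that of NK cell-like cells was -0.14 and that of dendritic-like cells -1.14. With doublets kept that of tumour-like cells was -1.74, as cluster 6 and most of cluster 2 went to an unnamed cluster.

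With at least 30 UMIs per gene more genes are measured, so the counts at least 2-fold higher and lower were 295 and 121 in NK cell-like, 419 and 109 in T cell-like, 616 and 268 in dendritic-like, 391 and 128 in monocyte/macrophage-like and 933 and 591 in tumour-like cells. Between Y-positive cells, where fewer genes and list members reach 100 UMIs, they were 31 and 70 in NK cell-like, 18 and 58 in T cell-like and 57 and 91 in monocyte/macrophage-like cells, and 98 higher in dendritic-like cells.

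Between Y-positive cells the interferon median was -0.019 in NK cell-like cells over 8 members, -0.15 in T cell-like cells over 21 (the values of -0.10 and -0.19 elsewhere use all members measured over all cells), 1.18 in dendritic-like cells, 0.048 in monocyte/macrophage-like cells and -0.21 in cluster 4. In T cell-like cells MHC class II was -0.35, S phase -0.59, Il17a -1.75, Lgals7 -0.45 and Gzmk 0.33. In dendritic-like cells S phase was -0.48 and G2/M 0.26, and in monocyte/macrophage-like cells inflammatory cytokines 0.065 and angiogenesis -0.23. In cluster 4 S phase was 0.35, G2/M 0.030, hypoxia and glycolysis -0.13, inflammatory cytokines 0.24 and F10 -0.29, and in cluster 17 immediate early genes -0.068.

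With the looser filter the interferon median was 0.51 in T cell-like and 0.32 in monocyte/macrophage-like cells and Gzmg 0.30 in T cell-like cells, a class then holding cluster 17. In tumour-like cells, a class then holding 119 of the 124 neuroblast-like cells, 780 genes were at least 2-fold higher, and the medians were 0.28 for synapse, 0.34 for neuronal differentiation, 0.72 for astrocyte, -0.62 for G2/M and 0.60 for MHC class I genes, with Sox11 at 0.79. With doublets kept the interferon median was 0.50 and Gzmg 0.066 in T cell-like cells, which again held cluster 17. In tumour-like cells, a class then lacking cluster 6 and most of cluster 2, 247 genes were higher and 212 lower, and the medians were -0.11 for neuronal differentiation, -0.86 for oligodendrocyte, 0.50 for astrocyte, -0.13 for S phase, 0.32 for G2/M and 1.12 for MHC class II genes.

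With the mean over cells Gzme was -0.19 in NK cell-like cells, 236 genes were lower in dendritic-like cells, and the interferon median was 0.14 in T cell-like, 1.23 in dendritic-like and 0.45 in monocyte/macrophage-like cells. In tumour-like cells the medians were -0.57 for oligodendrocyte, -0.85 for G2/M, -0.56 for hypoxia and glycolysis, 0.66 for interferon, 0.58 for MHC class I and 1.38 for MHC class II genes.

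With clusters weighted alike S phase was -0.60 in T cell-like cells and -0.68 in dendritic-like cells, where interferon was 1.07. In tumour-like cells 259 genes were higher, and the medians were -0.032 for neuronal differentiation, -0.58 for oligodendrocyte, 0.40 for astrocyte, -0.25 for S phase, -0.084 for G2/M, -0.54 for hypoxia and glycolysis, 0.51 for interferon, 0.60 for MHC class I and 1.03 for MHC class II genes. With members passing the screen the tumour-like medians were -0.38 for neuronal differentiation, -0.023 for neural stem and progenitor, 0.79 for interferon, 1.14 for MHC class II and -0.81 for suppressive macrophage genes, and p53 targets in cluster 17 were at -0.35.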

Other observations

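Tests in this part were chosen only after the result was seen. Genes of cholesterol synthesis and its regulation, other than those named in the report, were lower in tumour-like cells of the library labelled knockout: 18 of 19 measured genes were at least 1.5-fold lower and 0 higher (median log2 ratio -1.47), below all matched random lists. Idi1, an isomerase of the pathway, stood at 47.0 and 4.35 CPM, the sterol carrier gene Stard4 was 6.95-fold and Sqle 3.96-fold lower, while Ebp was within 1.04-fold. The list was lower in dendritic-like cells (10 of 14, median -0.71), monocyte/macrophage-like cells (6 of 11, -0.60), cluster 4 (7 of 17, -0.54) and cluster 17 (4 of 7, -0.64), and nearer to 0 in T cell-like cells (4 of 15, -0.19) and NK cell-like cells (1 of 4, -0.11). Single genes were lower there too. The named genes Fdps and Cyp51 were at least 1.5-fold lower in all 6 host groups compared (median log2 ratios -1.115 and -0.98). Idi1 was lower in all 5 where it was measured (-1.15), T cell-like cells included. Hmgcs1 was not among the genes shifted alike in host classes.

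Cacnb2, which encodes a subunit of voltage-gated calcium channels, was higher under the knockout label in the 3 host groups where it was measured, with a median log2 ratio of 2.38, but it did not pass the screen against RNA from other cells. Cluster 31, B cell-like cells led by Ighg1, Igkc and Jchain, held 2 cells under the wild type label and 53 under the knockout label. All 2464 and 85 barcodes under 200 UMIs had a human-gene UMI, against 58.6% and 70.4% of the others, and 176 of those under the wild type label held more human than mouse UMIs. Those 2464 barcodes held 2497 human UMIs in total, so nearly all had a single human UMI. Most of the 176 thus had no mouse UMI, and they do not show human cells. Among barcodes of 200 UMIs or more, 0 held more human than mouse UMIs in either library.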
